A study of Rattus norvegicus with 46 samples.

How the data were processed

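Villus sections of the rat duodenum were profiled on Affymetrix rat arrays, with 1 array per rat and segment. Control, iron-deficient and iron-repleted Wistar rats and 3 groups of Belgrade rats gave 44 arrays from 22 rats, each rat with 1 array of the villus top and 1 of the villus bottom. A further 2 arrays held the lower and the upper crypt of 1 more Wistar rat from a separate experiment. The age was given as 1 month for the Wistar rats of the villus groups, for the low-iron rats at the start. No age was given for the Belgrade rats. The low-iron rats were bled 2 to 3 ml every 3 days for 4 weeks, and the repleted ones then drank 50 µM ferric ammonium citrate for 3 days.

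The deposited values are intensities on a linear scale, 1 per probe set and array. The signal algorithm of the authors is not stated. The values themselves show that each array had been scaled by the authors to 1 trimmed mean, 2500 intensity units on 42 arrays and 2875 on 4 arrays, a ratio of 1.15. Such scaling fixes the mean of each array, so a shift shared by most genes cannot be seen. The deposited data held 31099 probe sets, of which 57 control probe sets were left out, and the probe-set annotation gave exactly 1 gene symbol for 20826 of the others. Genomic positions are not given, because the deposited values name no genome build.

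A pseudocount of 44 intensity units, the 10th percentile of the villus values, was added before the log2 transform. Array medians on the log2 scale spanned 0.98, more than the 0.5 allowed, so the villus arrays were quantile normalized (limma version 3.58.1 in R version 4.3.3, with the data.table package, version 1.17.8). Probe sets were kept if at least 3 villus arrays exceeded the 40th percentile of their array, which left 26517 of 31042. The comparisons, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The written plan gave the number of villus rats as 23, a slip of addition, and 22 is the number in the labels.

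The arrays of control rats 1 and 2 were nearly identical in both segments, and so were those of Belgrade rats 1 and 2 on a normal diet. Over 5464 bright probe sets the robust SD of their differences was 0.138 to 0.173, against 0.223 to 0.727 for the other pairs of rats among the 30 compared. Each of these pairs was averaged and counted as 1 sample, by a limit of 0.2 chosen after the arrays had been compared, which left 20 counted samples. Whether they are repeats of 1 animal is not known. Counting all 22 rats separately, as first planned, is an alternative. The top and bottom arrays of a rat belong together by their labels, and this was checked in the values. Xist was above or below a log2 level of 12 in both segments alike in all 22 rats. After the group means were taken off, the top array correlated best with the bottom array of the same rat in 19 of 22 rats, although these correlations were low, 0.214 at most. Rat numbers were not taken to pair rats between groups, since in 0 of 15 pairs of groups did all same-number rats correlate above 0.1.

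Groups were compared with limma (lmFit, eBayes with a trend) on each sample's mean of top and bottom, in 1 fit of 6 groups that shares the spread. Top and bottom were compared through the difference within each rat. The same group comparisons were run for the top and the bottom arrays alone as secondary tests. P values were adjusted by Benjamini-Hochberg over all probe sets, and a probe set was called at an adjusted p under 0.05. All adjusted p values for single genes are from limma and are two-sided.

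A total of 23 gene lists was tested with camera (limma) at its preset correlation of 0.01, with 1 probe set per gene, the brightest, and adjustment over 207 tests (23 lists in 9 comparisons). The lists cover iron handling, hypoxia-inducible genes, copper and zinc handling, heme, mitochondrial respiration, brush border digestion and transport, lipid absorption, cholesterol synthesis, cell cycle, stem and transit cells, oxidative stress, xenobiotic metabolism, the circadian clock, and immediate early and heat shock genes. The others are markers of cells that sections could hold: Paneth, goblet, enteroendocrine, Brunner's gland and gastric mucosa, smooth muscle and stroma, lymphocyte, plasma and antigen-presenting cells, mast cells, red blood cells and exocrine pancreas. Named genes are 5 iron transport genes always (Slc11a2, Cybrd1, Slc40a1, Heph, Tfrc), other iron handling genes called, up to 8 called probe sets with the largest rise and 8 with the largest fall among those that separate every sample of the groups, and up to 4 called members of each called list. Fth1 and Ftl1 were on that list too but had no probe set with a single symbol and are not reported here.

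The fit was tested on simulated normal values with the spread of each probe set. Of simulated 2-fold changes (log2 of 1) between deficient and control rats, 33.3% were called, and 66.7% at a log2 of 2 and 90.9% at a log2 of 3, with a mean of 6.33 false calls among 26517 probe sets. For top against bottom in control rats the shares were 15.9%, 47.3% and 71.7%, and for the difference between segments in the iron deficiency effect 2.99%, 28.9% and 37.4%.

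The alternatives were the values as deposited, median centring, no filter and a stricter filter at the 60th percentile, a pseudocount of 11 or 176, eBayes without a trend, only the groups compared, a fit that takes rat number as replicate block, a fit with no pairing of top and bottom, a fit of all 44 arrays with the rat as a random block for the segments, an estimated correlation for the lists, and leaving out each sample in turn. Chosen after the data were seen were the merging of near-identical rats, a fit without iron-repleted rat 3, a fit with the Xist level of each rat as covariate, an estimated correlation for the lists without iron-repleted rat 3, and the repeats of the overlap and the reversal under other settings. A planned split of the 4 control rats into 2 and 2 for the overlap was not run, because 3 counted control samples remained.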

Results

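Gene expression was measured along the duodenal villus of rats that differed in iron supply. Belgrade rats carry a mutation of Slc11a2, the iron transporter of the apical membrane also called DMT1, on a Wistar background. There were 4 control, 4 iron-deficient and 3 iron-repleted Wistar rats, and 4 Belgrade rats on a normal diet, 4 fed iron for 3 days and 3 fed iron for 6 days. After near-identical rats had been averaged, the counted samples were 3, 4, 3, 3, 4 and 3 in that order. The median intensity of the 44 villus arrays lay between 597 and 1179. Levels are log2 normalized intensities and changes are differences of log2 levels. Rats with a high Xist level, the transcript of the inactive X chromosome, numbered 1, 0, 1, 1, 1 and 3 in the 6 groups.

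Iron-deficient and control Wistar rats were compared to find what a lack of dietary iron with bleeding changes in the villus. Cybrd1, a ferric reductase of the brush border, rose by 2.13 ± 0.43 (SE, adjusted p = 0.0350), from a level of 14.33 ± 0.11 (SD, n = 3) to 16.46 ± 0.72 (SD, n = 4). The less bright of the 2 probe sets of Slc11a2 rose by 2.02 ± 0.39 (SE, adjusted p = 0.0350), from 12.81 ± 0.27 (SD, n = 3) to 14.83 ± 0.52 (SD, n = 4). Its brighter probe set differed by 1.40 ± 0.36 (SE, adjusted p = 0.0755), with means of 15.55 and 16.95. Hmox1, which breaks down heme, rose by 1.94 ± 0.32 (SE, adjusted p = 0.0197). Slc40a1, the iron exporter ferroportin, differed by 1.00 (adjusted p = 0.0848), Heph, the ferroxidase hephaestin, by 0.72 (adjusted p = 0.149) and the transferrin receptor Tfrc by 0.16 (adjusted p = 0.878), none of which passed. A less bright probe set of Tfrc differed by 1.08 and did not pass either (adjusted p = 0.255).

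In the same comparison 107 of 26517 probe sets passed, 72 higher and 35 lower in iron deficiency. The largest rises were in Alox15, an arachidonate lipoxygenase (4.37), Slc30a1, a zinc exporter (2.77), Areg, a ligand of the epidermal growth factor receptor (2.40), Vtcn1 (2.34), Zfp68 (2.31) and Fndc3b (2.07), where for Zfp68 and Fndc3b the brighter probe sets of the gene did not pass. Alox15 went from 7.55 ± 0.52 (SD, n = 3) to 11.92 ± 0.79 (SD, n = 4). The control level is in the dim range, so the size of this rise depends on the pseudocount, with 3.61 for the larger and 4.71 for the smaller one. For Slc30a1 these values were 2.21 and 3.07, for Vtcn1 1.42 and 3.01 and for Fndc3b 1.47 and 2.38, so the ranks are not firm. The largest falls were in Aqp8, a water channel (-3.60), Ighl2 (-2.62), Pou2af1, a coactivator of B cells (-1.87), Klf15 (-1.82), Aebp1 (-1.65), Slc6a20a, an imino acid transporter (-1.54), Sorl1 (-1.44) and Aqp1 (-1.38). For Klf15 and Sorl1 the brightest probe set did not pass (adjusted p = 0.0658 and 0.0611). With the smaller pseudocount Aqp8 (adjusted p = 0.0568), Sorl1 (0.0563), Zfp68 (0.0563) and Slc16a3 (0.0503) no longer passed, and with the larger one Klf15 (0.0577). Pou2af1 was at -1.36 with the larger and -2.13 with the smaller pseudocount.

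Cholesterol synthesis was the list with the largest median among those called higher in iron deficiency apart from red blood cell markers. Its 14 measured genes were all higher, with a median of 1.21 (adjusted p = 7.29e-17, and adjusted p = 0.127 with an estimated correlation). Of these, 6 passed over all probe sets and 12 when adjusted over the list alone, among them Msmo1 (1.89), Insig1 (1.46), Cyp51 (1.40) and Nsdhl (1.00). Hypoxia-inducible genes had a median of 0.43 over 29 genes (adjusted p = 5.37e-11, and adjusted p = 0.138 with an estimated correlation), with 3 that passed over all probe sets, Slc16a3, a lactate exporter (1.66), Egln3, an oxygen-dependent hydroxylase (1.18) and Car9, a carbonic anhydrase (0.99), and 14 when adjusted over the list alone. Iron handling had a median of 0.16 over 21 genes (adjusted p = 0.00424, and adjusted p = 0.368 with an estimated correlation), with 2 genes past the test and 6 when adjusted over the list alone, all higher. The lists of oxidative stress (median 0.40) and immediate early and heat shock genes (0.50) were higher too, with adjusted p = 0.466 and 0.461 with an estimated correlation. For the 12 heme genes the median was -0.03 and the mean 0.32, and the list did not pass (adjusted p = 0.106), but did without iron-repleted rat 3 in the shared spread (adjusted p = 0.0226, and adjusted p = 0.146 with an estimated correlation).

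Markers of other cells moved with iron deficiency as well. Smooth muscle and stroma markers had a median of -0.71 (adjusted p = 1.33e-08, and adjusted p = 0.368 with an estimated correlation), all 16 lower, with Col6a1 (-0.96) past the test and 9 when adjusted over the list alone. In the bottom arrays the mean level of these markers was 13.28, 13.35, 15.72 and 14.31 in control rats 1 to 4 and 12.89 to 13.30 in the deficient rats. Lymphocyte, plasma and antigen-presenting cell markers had a median of -0.51 (adjusted p = 0.000338, and adjusted p = 0.314 with an estimated correlation), and the 4 red blood cell markers a median of 1.43 (adjusted p = 0.00305, and adjusted p = 0.382 with an estimated correlation). Cell cycle genes had a median of -0.31 (adjusted p = 0.00692, and adjusted p = 0.643 with an estimated correlation). The mitochondrial list had a median of -0.15, which turned to 0.06 with median centring and did not pass there or with the values as deposited, and adjusted p = 0.461 with an estimated correlation.

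The count of 107 rested on the samples and the settings used. It was 2 without control sample 1-2, 14 without control rat 3, 32 without control rat 4, 2, 0 and 3 without deficient rats 1, 2 and 3, 171 without deficient rat 4, 488 without iron-repleted rat 3 in the shared spread, 7 with median centring, 0 without a trend, 9 with Xist as covariate and 680 with all 22 rats counted separately. With the values as deposited 128 passed, 55 higher and 73 lower, beside a median over all probe sets of -0.14.

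Iron-repleted rats were compared with iron-deficient rats to see what 3 days of iron in the drinking water change. No probe set passed in limma (0 of 26517), and 3385 had an unadjusted p under 0.05. Slc11a2 differed by -0.66 ± 0.36 (SE, adjusted p = 0.453), Cybrd1 by -0.79 ± 0.43 (SE, adjusted p = 0.457), Heph by -0.66 (adjusted p = 0.261), Slc40a1 by -0.47 (adjusted p = 0.471) and Tfrc by -0.36 (adjusted p = 0.692). The less bright probe set of Tfrc differed by -0.95 (adjusted p = 0.368). The repleted rats were far apart. Slc11a2 had means of 16.86, 17.31 and 14.70 in repleted rats 1, 2 and 3, beside a control mean of 15.55. Cybrd1 had 15.93, 16.87 and 14.21 in the same rats and 14.33 in controls, and Alox15 had 11.47, 12.10 and 7.65 and 7.55 in controls. For Slc11a2 and Cybrd1 the low means of rat 3 lay mainly in its bottom array, at 12.46 and 11.48, beside 16.95 and 16.93 at its top. Smooth muscle and stroma markers in that bottom array were at 15.53, against 13.32 and 13.39 in those of repleted rats 1 and 2. Alox15 was low in both arrays of rat 3, at 6.51 and 8.78. The top array of rat 3 also had the highest median intensity of all, 1179, and the lowest mean correlation with its own group, 0.752.

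Among the lists, goblet cell markers were lower after repletion by a median of -0.52 (adjusted p = 3.24e-05, and adjusted p = 0.0807 with an estimated correlation), 5 of 9 lower when adjusted over the list alone, and without rat 3 the median was -0.47. Cholesterol synthesis genes had a median of -0.59 (adjusted p = 3.33e-05, and adjusted p = 0.461 with an estimated correlation), which became -0.18 without rat 3 (adjusted p = 0.0736). Heme genes had a median of -0.41 (adjusted p = 0.00548, and adjusted p = 0.466 with an estimated correlation), and -0.09 without rat 3 (adjusted p = 0.600). Smooth muscle and stroma markers had a median of 0.53 (adjusted p = 0.000185, and adjusted p = 0.476 with an estimated correlation), and 0.18 without rat 3 (adjusted p = 0.138). With median centring their median was 0.19, beside a median over all probe sets of -0.20. Without rat 3 lipid absorption (0.31, adjusted p = 0.0142) and exocrine pancreas (-1.10, adjusted p = 0.0417) passed instead, with adjusted p = 0.538 and 0.706 with an estimated correlation. The count of 0 became 511 without deficient rat 4, 87 without repleted rat 1 and 16 without repleted rat 2.

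Of the 107 probe sets called in iron deficiency, 93 (86.9%) had the opposite sign after repletion, and 0 were called in the opposite direction. Unchanged simulated groups that share the deficient rats gave 90.0%. These groups hold no true deficiency effect, while the 107 passed a test for one, so the simulated share is no chance level for them. The share of opposite signs therefore cannot tell whether iron reversed the changes. In fits without repleted rat 3 the share was 74 of the same 107 (69.2%, simulated 86.8%). It was 334 of the 488 probe sets called in those fits (68.4%, simulated 83.5%), with 0 called in the opposite direction in either set.

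Iron-repleted rats were also compared with control rats, to see what still differed from normal feeding. A total of 18 probe sets passed, 9 higher and 9 lower. Slc34a2, a phosphate transporter, fell by 3.46 (adjusted p = 0.0409), from 10.72 ± 0.35 (SD, n = 3) to 7.26 ± 0.30 (SD, n = 3). The repleted level is in the dim range, and the difference was -2.61 with the larger and -3.86 with the smaller pseudocount. Other falls were in Tet3 (-1.81), Stard13 (-1.31), the splicing kinase Clk4 (-1.17), Nufip2 (-1.15), Srrm2 (-1.14), Hnrnpa1 (-1.08) and Bcl2l2 (-0.90). Rises were in Fntb, a farnesyltransferase subunit (1.82), Ddx3x-ps1 (1.73), Egln3 (1.33), Dyrk2 (1.33), Rab6a (1.06), Mtpn (0.99), Bmpr1a (0.97) and Rac1 (0.93). In each direction 1 more probe set passed, without a single gene symbol. For Dyrk2, Rab6a, Rac1, Tet3 and Hnrnpa1 the brightest probe set of the gene did not pass. Slc11a2 differed by 0.74 (adjusted p = 0.372), Cybrd1 by 1.34 (adjusted p = 0.172), Slc40a1 by 0.53 (adjusted p = 0.388), Heph by 0.06 (adjusted p = 0.936) and Tfrc by -0.19 (adjusted p = 0.846).

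In that comparison hypoxia-inducible genes had a median of 0.31 (adjusted p = 1.00e-08, and adjusted p = 0.226 with an estimated correlation), with 11 genes higher when adjusted over the list alone, and a median of 0.50 without repleted rat 3. Cholesterol synthesis genes had a median of 0.54, all 14 higher (adjusted p = 8.91e-06, and adjusted p = 0.450 with an estimated correlation), and 1.00 without repleted rat 3. Exocrine pancreas markers had a median of -2.06 (adjusted p = 0.00763, and adjusted p = 0.697 with an estimated correlation), all 12 lower; their mean level was 14.43 and 14.41 in the bottom arrays of control rats 1 and 2, 8.04 and 8.27 in those of control rats 3 and 4, and 8.04 to 8.25 in those of the repleted rats. Lymphocyte markers (median -0.54), the mitochondrial list (-0.16), cell cycle (-0.29), goblet cell (-0.20) and immediate early genes (0.52) passed as well, with adjusted p = 0.395, 0.466, 0.713, 0.368 and 0.461 with an estimated correlation. The calls of cell cycle and goblet cell genes ended both with the values as deposited and with median centring, and that of exocrine pancreas with median centring. Without repleted rat 3 immediate early genes did not pass (adjusted p = 0.104). Iron handling (0.32), oxidative stress (0.36), brush border (0.27), lipid absorption (0.24), Paneth cell (-0.95), smooth muscle and stroma (-0.62) and red blood cell (1.56) lists then did. With an estimated correlation in that fit their adjusted p was 0.0268, 0.349, 0.627, 0.596, 0.381, 0.352 and 0.254. The count of 18 was 0 without control sample 1-2, without control rat 3 or without repleted rat 2, 1 without control rat 4, 123 without repleted rat 1, 299 without repleted rat 3, 0 with median centring, 0 without a trend, 57 with Xist as covariate and 606 with all 22 rats counted separately. With the values as deposited it was 12, with 2 higher and 10 lower.

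Belgrade rats on a normal diet were compared with control Wistar rats for the effect of the genotype. Alox15 rose by 4.67 ± 0.75 (SE), from 7.55 ± 0.52 (SD, n = 3) to 12.22 ± 0.74 (SD, n = 3). A less bright probe set of Atp7a, a copper exporter, rose by 1.60 ± 0.26 (SE), and Egln3 by 1.58 ± 0.25 (SE). The other 2 probe sets of Atp7a, the brightest among them, did not pass (1.58 and 2.08, adjusted p = 0.0602 and 0.326). These 3 were the probe sets past the test (adjusted p = 0.0329 for each, 3 higher and 0 lower), and 1592 had an unadjusted p under 0.05. The rise of Alox15 was 3.89 with the larger and 5.01 with the smaller pseudocount. Cybrd1 differed by 2.33 ± 0.46 (SE, adjusted p = 0.127), with means of 14.33 and 16.65. The brightest probe set of Slc11a2 differed by 1.48 (adjusted p = 0.300), its other probe set by 2.19 (adjusted p = 0.0985), Slc40a1 by 1.04 (adjusted p = 0.379), Tfrc by 1.05 (adjusted p = 0.650) and Heph by 0.55 (adjusted p = 0.823). The less bright probe set of Tfrc differed by 1.73 (adjusted p = 0.359). Genotype cannot be separated from any difference in age or in when the strains were studied, since no age of the Belgrade rats and no dates are given.

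Cholesterol synthesis genes were higher in Belgrade rats by a median of 0.93, all 14 in that direction (adjusted p = 9.87e-17, and adjusted p = 0.127 with an estimated correlation), with 11 when adjusted over the list alone. Hypoxia-inducible genes had a median of 0.54 (adjusted p = 7.12e-16, and adjusted p = 0.0807 with an estimated correlation), with 15 of 29 when adjusted over the list alone. Iron handling had a median of 0.36 (adjusted p = 6.41e-05, and adjusted p = 0.138 with an estimated correlation), with 5 of 21, and goblet cell markers 0.29 (adjusted p = 6.41e-05, and adjusted p = 0.0807 with an estimated correlation), with 2 of 9. With the values as deposited the iron handling median was 0.19, beside a median over all probe sets of -0.13. Heme genes (0.15), immediate early genes (0.41) and clock genes (0.45) passed as higher, with adjusted p = 0.466, 0.386 and 0.368 with an estimated correlation. Smooth muscle and stroma markers were lower (median -0.66) and red blood cell markers higher (1.29). With an estimated correlation the adjusted p was 0.368 for both lists. The deficient rats gave the same directions against the same control samples, so the match is no independent repeat. In the bottom arrays of control rats 1 to 4 the stroma markers were at 13.28, 13.35, 15.72 and 14.31, and these levels enter both comparisons. Lymphocyte markers (-0.45), cell cycle genes (-0.30) and the mitochondrial list (-0.09) passed as lower, with adjusted p = 0.386, 0.713 and 0.523 with an estimated correlation, and the mitochondrial median turned to 0.11 with median centring. The calls of cell cycle and mitochondrial genes ended with median centring and with the values as deposited. The count of 3 was 0 or 1 without any 1 of the 6 samples compared, 64 without iron-repleted rat 3 in the shared spread, 1 with the values as deposited, 0 without a trend, 5 with Xist as covariate and 48 with all 22 rats counted separately.

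Across 26517 probe sets the deficiency effect and the Belgrade effect had a correlation of 0.655, across genes that are not independent replicates. Both use the same control samples, and unchanged simulated groups sharing them gave 0.535. The observed covariance was 0.156, and it exceeded the simulated one by 0.0557. In both effects 3 probe sets were called higher. Independent comparisons would give 0.00815, a value that is too low for effects with shared controls. All probe sets called in iron deficiency (100%) had the same sign in Belgrade rats, a share that shared controls alone push upward.

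**Figure D1:**
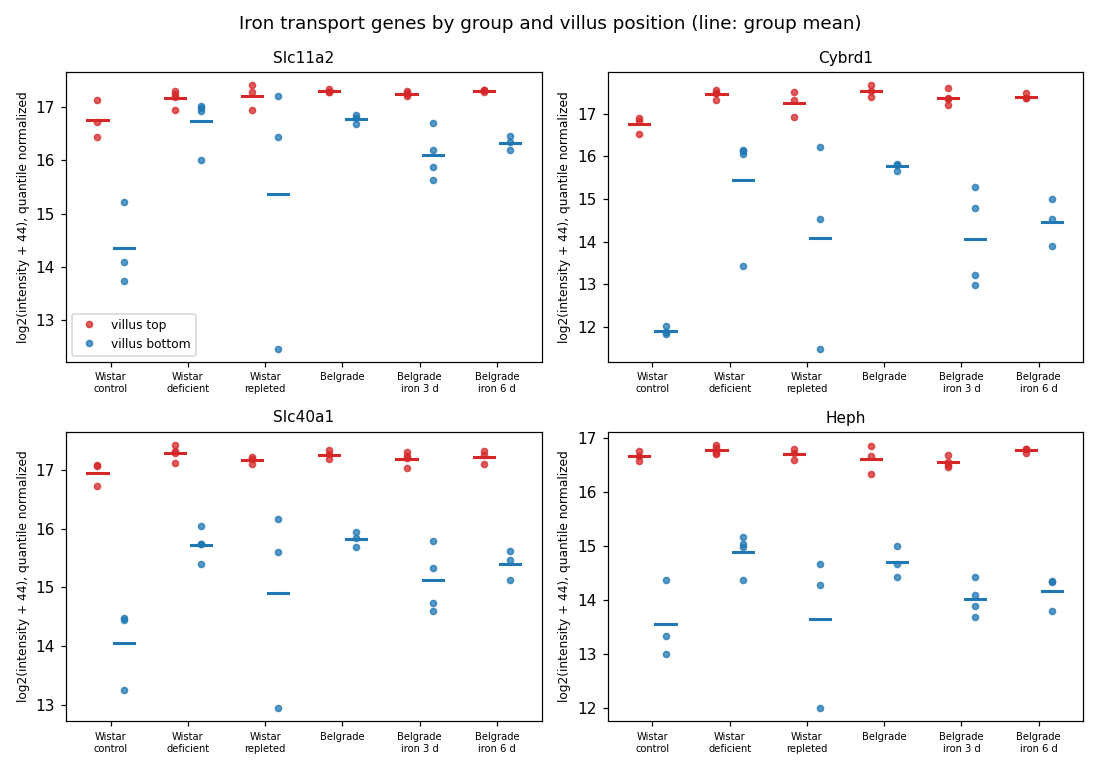
Log2 normalized intensity of Slc11a2, Cybrd1, Slc40a1 and Heph (vertical axes) in the 6 groups (horizontal axes), with 1 point per counted sample at the villus top (red) and bottom (blue) and bars at the group means. At the bottom Cybrd1 lies at 11.90 in control and 15.45 in iron-deficient rats on average, while the top means are 16.76 and 17.47.

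Belgrade rats fed iron for 3 and 6 days were compared with Belgrade rats on a normal diet. Cybrd1 differed by -0.93 ± 0.43 (SE) after 3 days and by -0.72 ± 0.46 (SE) after 6 days, with means of 16.65, 15.73 and 15.94 in unfed, 3-day and 6-day rats. Slc11a2 differed by -0.36 and -0.22, Slc40a1 by -0.39 and -0.23, Heph by -0.37 and -0.19 and Tfrc by -0.03 and -0.15, and the adjusted p was 1.00 for each of these values. No probe set passed in limma at 3 days (0, with 730 at an unadjusted p under 0.05) or at 6 days (0, with 1120).

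At the level of lists, brush border genes were lower after 3 days by a median of -0.52, all 17 in that direction (adjusted p = 4.00e-08, and adjusted p = 0.422 with an estimated correlation), and by -0.36 after 6 days (adjusted p = 0.00493, and adjusted p = 0.697 with an estimated correlation). Cell cycle genes had a median of 0.28 after 3 days, 24 of 27 higher (adjusted p = 0.000372, and adjusted p = 0.466 with an estimated correlation). Oxidative stress genes had medians of -0.34 and -0.39 (adjusted p = 0.550 and 0.461 with an estimated correlation) and hypoxia-inducible genes -0.10 and -0.07 (adjusted p = 0.644 and 0.665 with an estimated correlation). After 3 days copper and zinc handling (-0.21), lipid absorption (-0.20), xenobiotic metabolism (-0.30), lymphocyte markers (-0.11), clock genes (-0.34) and immediate early genes (-0.47) passed as lower, with adjusted p = 0.368, 0.733, 0.520, 0.515, 0.386 and 0.461 with an estimated correlation. After 6 days cholesterol synthesis genes had a median of -0.48, all 14 lower (adjusted p = 3.88e-07, and adjusted p = 0.386 with an estimated correlation). Clock genes had a median of -0.85 (adjusted p = 0.000738, and adjusted p = 0.127 with an estimated correlation), with 7 of 13 past the test when adjusted over the list alone, 6 of them lower. With median centring the 3-day call of clock genes and the 6-day call of hypoxia-inducible genes ended. Without iron-repleted rat 3 in the shared spread iron handling passed as lower at both times (-0.10 and -0.19, adjusted p = 0.0126 and 0.0174, and adjusted p = 0.109 and 0.140 with an estimated correlation). Smooth muscle and stroma markers were higher after 6 days by 0.46, all 16 in that direction (adjusted p = 0.414 with an estimated correlation), and stem and transit cell markers by 0.20 (adjusted p = 0.466 with an estimated correlation). Apart from clock genes, the lists lower after 3 days were higher at the villus top in control rats, such as brush border genes (3.38). Cell cycle genes, higher after 3 days, were lower at that top (-2.62), as were stem and stroma markers (-2.37 and -1.18). Sections taken lower on the villus would shift these lists in the same way. That was not tested here, so an effect of iron cannot be told apart from section height. All 3 rats of the 6-day group had a high Xist level, against 1 of 4 unfed Belgrade rats.

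**Figure D2:**
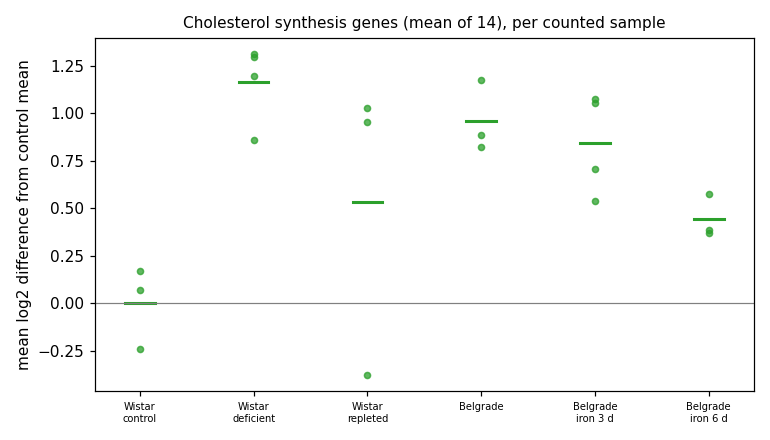
Mean log2 difference from the control mean over the 14 cholesterol synthesis genes (vertical axis) in the 6 groups (horizontal axis), with 1 point per counted sample and bars at the group means. The median of the gene changes is 1.21 for iron-deficient and 0.93 for Belgrade rats, and 1 repleted rat, rat 3, lies below the control mean.

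The 3-day iron responses of Belgrade and Wistar rats were compared by their interaction. The start states differ, since the Wistar rats came from a low-iron diet. No probe set passed in limma (0, with 1956 at an unadjusted p under 0.05), and the count was 2 without deficient rat 4 or without repleted rat 1. The difference for Slc11a2 was 0.30 ± 0.51 (SE, adjusted p = 0.922) and for Cybrd1 -0.14 ± 0.61 (SE, adjusted p = 0.970). Slc40a1 (0.08), Heph (0.29) and Tfrc (0.33) did not pass (adjusted p = 0.971, 0.877 and 0.906). Among the lists, goblet cell markers differed by a median of 0.52 (adjusted p = 0.000146, and adjusted p = 0.0807 with an estimated correlation), with 4 of 9 when adjusted over the list alone. Which other lists differed depended on repleted rat 3.

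The top and bottom of the villus were compared within each rat, to see where along the villus genes are expressed. In control rats the heme and folate transporter Slc46a1 was higher at the top by 5.28 ± 0.46 (SE), the ferric reductase Cybrd1 by 4.86 ± 0.61 (SE), Heph by 3.10 ± 0.38 (SE), Slc40a1 by 2.90 ± 0.41 (SE) and Slc11a2 by 2.42 ± 0.55 (SE), while Tfrc was lower by a difference of -2.17 ± 0.42 (SE). Ireb2, an iron regulatory protein, was higher at the top by 4.03 ± 0.31 (SE). The adjusted p was 0.00401 for Slc11a2, 0.00106 for Tfrc and 2.97e-05 for Cybrd1, with every counted control sample in the same direction. Of the 21 iron handling genes, 11 were called higher and 5 lower at the top. The largest rises were in Areg (6.38), the apolipoprotein Apoa4 (6.06), Stfa3 (5.74), Cda (5.53), Rdh7 (5.47), the water and glycerol channel Aqp7 (5.37) and Sectm1b (5.30), and the largest falls in Grem1 (-6.72), Mfap4 (-5.28), Postn (-5.16), Vip (-5.10), Dpt (-4.92), Pla2g2a (-4.76), Aspn (-4.63) and Pcp4 (-4.63), several of them genes of stroma or nerve fibres.

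All 17 brush border genes passed as higher at the top in control rats (median 3.38, adjusted p = 1.41e-10, and adjusted p = 0.386 with an estimated correlation), among them Mep1a (4.47), Slc3a1 (4.07) and Slc15a1, a peptide transporter (3.84). Lipid absorption genes (median 2.45, 15 of 20 higher), xenobiotic metabolism (2.74, 11 higher and 1 lower of 14), hypoxia-inducible genes (0.44, 11 of 29 higher), immediate early and heat shock genes (1.19) and lymphocyte markers (1.31), with Gzmb (4.58) and Gzma (4.06) of cytotoxic cells, were higher at the top. With an estimated correlation their adjusted p was 0.368, 0.386, 0.0807, 0.127 and 0.368. Oxidative stress genes (0.69), copper and zinc handling (0.60) and iron handling (0.82) passed too, with adjusted p = 0.520, 0.466 and 0.466 with an estimated correlation. All 27 cell cycle genes passed as lower at the top (median -2.62, adjusted p = 6.45e-11, and adjusted p = 0.217 with an estimated correlation), such as Mcm5 (-3.58) and Ube2c (-2.83). Stem and transit cell markers (-2.37, 8 of 9), Paneth cell markers (-2.39, 5 of 8) and smooth muscle and stroma markers (-1.18, 6 of 16) were lower at the top, with adjusted p = 0.138, 0.466 and 0.749 with an estimated correlation. The mitochondrial list was lower (-0.30, 7 of 24), but its median turned to 0.18 with median centring (adjusted p = 0.773 with an estimated correlation). The calls of Paneth cell, smooth muscle and stroma, and mitochondrial genes ended with the values as deposited and with median centring.

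A total of 6420 probe sets passed in control rats, 3082 higher and 3338 lower at the top, and 14382 over all groups, 6757 higher and 7625 lower. With the values as deposited the control count was 7131, 2627 higher and 4504 lower, beside a median over all probe sets of -0.23. With median centring it was 6109, 3511 higher and 2598 lower, so the balance of directions depends on the scaling. Over all groups the values as deposited gave 5708 higher and 9001 lower. With the main settings the control count was 4803 without control sample 1-2, 4214 without control rat 3 and 4082 without control rat 4. Over all groups the largest rises were in Gprc5a (5.68), the tight junction gene Cldn4 (5.30), Dhrs9 (5.25), Areg (5.17) and Aqp3 (4.88), and the largest falls in Vip (-5.71), Grem1 (-5.69) and Dpt (-4.93). Slc46a1 was higher by 3.74, Cybrd1 by 3.01, Heph by 2.52, Slc40a1 by 2.01 and the brighter probe set of Slc11a2 by 1.22, and Tfrc differed by -1.86, each in the same direction in every counted sample. The less bright probe set of Slc11a2, which is further from the highest values, was higher at the top by 2.20. The hypoxia list had the lowest adjusted p with an estimated correlation of all the list tests, 0.0510 (median 0.93, 23 of 29 higher). None of the 79 list calls among the 207 tests held an adjusted p under 0.05 with an estimated correlation. Without iron-repleted rat 3, an alternative chosen after the data were seen, 14 of the 207 tests did. Enteroendocrine, Brunner's gland and gastric mucosa, and mast cell markers passed in no comparison, with smallest adjusted p values of 0.218, 0.0789 and 0.217.

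Whether the effects of iron deficiency and genotype differ between top and bottom was tested through the change in the difference within rats. No probe set passed for iron deficiency (0, with 2396 at an unadjusted p under 0.05 in limma) or for genotype (0, with 1711). At the bottom Cybrd1 differed by 3.55 ± 0.80 (SE, adjusted p = 0.114) between deficient and control rats and at the top it rose by 0.71 ± 0.16 (SE, adjusted p = 0.0290), and the difference between these effects was -2.84 (adjusted p = 0.303). Its top means, 16.76 and 17.47, were near the highest normalized value on any array, 18.11. For the brightest probe set of Slc11a2 the values were 2.39 and 0.41, with a difference of -1.98 (adjusted p = 0.438). Its top means, 16.76 and 17.17, lay near that value too. Its less bright probe set rose at the top by 1.41 (adjusted p = 0.0154), with a difference between the effects of -1.22 (adjusted p = 0.530). The counts of calls by segment were 259 at the top and 0 at the bottom for iron deficiency (3449 at an unadjusted p under 0.05), and 24 and 1 for genotype. Without iron-repleted rat 3 in the shared spread, 101 probe sets passed for the iron deficiency difference and 5 for the genotype difference.

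For the other segment comparisons, repleted against deficient rats gave 0 calls at the top and 0 at the bottom (3306 and 3291 at an unadjusted p under 0.05 in limma), and repleted against control rats gave 55 and 0 (2791 at the bottom). Belgrade rats fed iron for 3 days gave 0 and 0 (548 and 1020), and those fed for 6 days gave 0 at the top (1016) and 1 at the bottom.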

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

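Of the tests in this part, those of the height of the sections and of a low level in the controls were chosen only after the result had been seen.

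In the iron-deficient group 1 of 4 rats stood below the others by a large share of the group's range in 6 named genes. For Slc11a2 the gap was 0.871 of the range (16.47 against 17.06 in the next rat), for Cybrd1 0.943 (15.37 against 16.78), for Heph 0.871 (15.54 against 15.91), for Sorl1 0.860, for Cyp51 0.873 and for Tet3 0.834. The low rat for Slc11a2 and Cybrd1 was deficient rat 4, whose bottom level of Cybrd1 was 13.42. In Belgrade rats fed iron for 3 days 1 of 4 rats stood above the others for Slc30a1 (0.889 of the range), Aqp8 (0.869), Col6a1 (0.871), Fntb (0.860), Dyrk2 (0.886) and Bmpr1a (0.932), and 1 stood below for Egln3 (0.902). These are 13 of 90 tests on 45 genes in 2 groups, and chance alone marks about 1 in 20 groups, with genes that are not independent. Without deficient rat 4 the count for iron deficiency was 171 instead of 107, and for repletion 511 instead of 0 in limma, beside 3385 at an unadjusted p under 0.05 with all rats.

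The 3-day iron response differed between Belgrade and Wistar rats in 3 gene lists. The median difference was 0.58 for cholesterol synthesis, 0.52 for goblet cell markers and -0.45 for smooth muscle and stroma. With an estimated correlation the adjusted p was 0.643, 0.0807 and 0.520. Without iron-repleted rat 3 the goblet cell difference was 0.44, while the other 2 were 0.06 and -0.11 and did not pass (adjusted p = 0.794 and 0.136). Other lists then differed, namely brush border (-0.83), lipid absorption (-0.51), xenobiotic metabolism (-0.54), hypoxia-inducible (-0.24) and oxidative stress genes (-0.18). With an estimated correlation only the goblet cell list passed in that fit of the interaction (adjusted p = 0.0379). That rat was near or below the controls in Slc11a2, Cybrd1 and Alox15, so leaving it out is not independent of the outcome, and a wrong label was not tested. In Aqp8 its mean was 9.24, beside 10.69 to 13.04 in controls and 7.69 to 8.87 in deficient rats. That mean joins a top array at 12.04 and a bottom array at 6.44. At the top, controls were at 12.61 to 14.75 and deficient rats at 7.49 to 8.79. At the bottom, controls were at 8.77 to 11.33 and deficient rats at 6.65 to 9.41.

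At the villus bottom the median change of Slc11a2, Cybrd1, Slc40a1 and Heph was 2.03 in iron-deficient and 2.10 in Belgrade rats. Tested singly, 0 probe sets passed at the bottom for iron deficiency and 1 for genotype, so the rise itself is not settled. Bottom sections taken higher up the villus would raise all genes with such a top over bottom ratio alike. Among 10000 sets of 4 genes matched on that ratio, the change lay at percentile 99.96 in deficient and 100 in Belgrade rats, above the upper ends of 1.32 and 1.31 of the central 95% of these sets. The rise thus exceeded that of single genes drawn at the same ratio. These sets rose too and held genes that need not move together, so section height is left open. The ratio also varied for Slc11a2, at 16.43 at the top and 15.22 at the bottom in control sample 1-2, but 17.14 and 13.74 in control rat 3. An effect of iron supply is a candidate explanation found and tested on the same data, and strain differences outside Slc11a2 were not tested. Other tissue in the control bottom sections was not tested as a cause either. Smooth muscle and stroma markers were at 15.72 and 14.31 in control rats 3 and 4, against 12.89 to 13.30 in deficient rats. Pancreas markers were at 14.43 and 14.41 in control rats 1 and 2, but also at 15.86 in deficient rat 1.

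The median difference of cholesterol synthesis genes was 1.21 in iron-deficient and 0.93 in Belgrade rats, calls that did not hold with an estimated correlation (adjusted p = 0.127 in both), so the rise itself is not settled. Among 10000 lists matched on the control top minus bottom difference, the change lay at percentile 100 in deficient and 100 in Belgrade rats. The central 95% of these lists ended at 0.23 and 0.19. That difference was not stable for the cholesterol genes. Msmo1 was at 12.91 at the top and 13.94 at the bottom in control sample 1-2, but at 15.15 and 12.99 in control rat 3. The matched lists also held genes that need not move together, so another height of the sections is left open. A low level in the 3 control samples alone cannot be told apart from a shared rise. The comparison without controls, 6 days of iron against none in Belgrade rats, had a p of 0.0627 with an estimated correlation (camera), and 0.00711 without iron-repleted rat 3. Food intake and fasting could differ between groups and were not tested.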

How the results depend on the processing

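Of the settings below, the merging of near-identical rats in the main counts, leaving iron-repleted rat 3 out of all fits and the Xist covariate were chosen only after the data were seen, while counting 22 rats separately is the design as first written. Counts are of probe sets past the limma threshold, and with the main settings they were 107 for iron deficiency, 0 for repletion against deficiency (3385 at an unadjusted p under 0.05), 18 for repletion against control and 3 for Belgrade against control. With the values as deposited the Belgrade count was 1. Median centring gave 7 for iron deficiency and 0 for repletion against control. A stricter filter gave 162 and 48, with fewer probe sets to adjust for. A pseudocount 4 times larger gave 1 for the Belgrade effect between segments. Without a trend the counts were 0 for iron deficiency, 0 for repletion against control and 0 for Belgrade. A fit of only the groups compared gave 425 for iron deficiency, 6 for repletion against control, 11 for Belgrade, 2 for 6 days of iron, 3577 for top against bottom in controls and 1 for the deficiency effect between segments. Counting 22 rats separately gave 680, 606 and 48 for iron deficiency, repletion against control and Belgrade, with 107, 18 and 3 of the main calls among them, and 5 and 2 for the deficiency and Belgrade effects between segments. Whether the near-identical arrays are repeats of 1 animal was not tested, and if they are, counting them apart would understate the spread. With 22 rats counted separately as well, rat number as replicate block gave 1317 for iron deficiency, 2 for repletion against deficiency, 1606 for repletion against control, 91 for Belgrade and 1 for 3 days of iron, and the 44 arrays taken as independent, without a block, gave 3 and 3 for the effects between segments, so these are to be set against the counts of 22 separate rats. The rat numbers are not known to pair rats, so this block is no correction. Without iron-repleted rat 3 in any fit the counts were 488 for iron deficiency, 299 for repletion against control, 64 for Belgrade, 101 and 5 for the effects between segments, and the share of opposite signs after repletion was 68.4% of those 488, against 86.9% of 107. With Xist as covariate they were 9, 57 and 5. Without iron-repleted rat 3 92 gene lists passed, 73 of them among the 79 of the main settings. With an estimated correlation 0 gene lists passed, against 79, and with an estimated correlation without iron-repleted rat 3 14 did, 13 of them among the 79, a pairing of choices made after the results were seen. Leaving out each sample of the groups compared in turn gave 0 (without deficient rat 2) to 171 (without deficient rat 4) for iron deficiency, 0 to 511 (without deficient rat 4) for repletion against deficiency, 0 (without control sample 1-2) to 299 (without repleted rat 3) for repletion against control, 0 to 1 for Belgrade, 0 to 2 for the interaction, 0 to 1 for the deficiency effect between segments and 4082 to 4803 for top against bottom in controls. The cause was not tested except where named. The count for top against bottom over all groups ranged from 13790 to 14579 when a sample was left out. Among single named genes 1083 results under the alternatives kept their call or stayed without one, 26 gained a call and 373 lost it. The 1083 include iron transport genes that had no call to lose, so these numbers do not give the share of calls that held. A reversed sign was looked for only where the gene passed in the main or the alternative fit, and 0 were found. Genes that passed in neither were not checked for their direction. Of the counts by segment 41 were within 1.5 times and 31 moved. The split of control rats for the overlap was not run. Signal over background limits what can be said of dim genes, and 26517 of 31042 probe sets passed the filter on dim values.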

Other observations

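The 2 crypt arrays come from 1 rat without replicates, so they are given as values. They were quantile normalized apart from the villus arrays, so their levels are not on one scale with the villus levels above. The lower crypt exceeded the upper crypt in stem and transit cell markers by a median of 2.08, in cell cycle genes by 1.64 and in Paneth cell markers by 1.45, each at percentile 100 of 10000 lists matched on expression. Brush border genes (-1.37), lipid absorption (-1.16), lymphocyte markers (-1.01) and xenobiotic metabolism (-0.93) were lower there, each at percentile 0. The stem cell gene Lgr5 was at 10.91 in the lower and 7.86 in the upper crypt, and the defensin Defa24 at 16.45 and 12.44. Iron handling genes differed by a median of -0.16 (percentile 12.3), with Slc11a2 at 16.84 and 17.22 and Cybrd1 at 15.98 and 17.32.

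Marker levels showed other tissue in some sections. Exocrine pancreas markers were at 15.86 in the bottom array of deficient rat 1, at 14.43 and 14.41 in those of control rats 1 and 2, at 12.67 in Belgrade rat 3, at 13.12 in Belgrade rat 4 of the 3-day group and at 12.15 in rat 2 of the 6-day group. Smooth muscle and stroma markers were highest in the bottom arrays of control rat 3 (15.72) and repleted rat 3 (15.53).

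Of the tests below, that of more female rats was chosen only after the result had been seen, and its limit was tightened after its value was known. In Belgrade rats fed iron for 6 days the clock output genes Dbp, Tef, Per1, Per2, Per3, Nr1d1 and Nr1d2 differed by -2.31, -1.56, -0.13, -1.18, -2.82, -1.19 and -1.38. The opposite-phase genes Bmal1, Clock, Npas2, Nfil3 and Cry1 differed by 1.15, 0.43, 0.11, 0.46 and -0.37, the last against the pattern (adjusted p = 1.00 each). Killing at another time of day would move these sets in opposite ways. The median of the opposite-phase genes was 0.433, but their mean differed by 0.36 with a 95% interval from -0.20 to 0.92, which leaves it open. High-Xist rats of the other groups differed in output genes by -0.482, with an interval from -1.44 to 0.48 beside the 6-day change of -1.51. This rests on iron-repleted rat 3, which lay -1.73 from its group, while the other 3 high-Xist samples lay at 0.09, -0.44 and 0.08. Without that rat the difference was -0.08, with an interval from -1.11 to 0.95, so the data give no sign that high Xist goes with lower output genes. As the 6-day change has an interval from -2.75 to -0.27, which overlaps both, more females in the 6-day group is not excluded. An effect of iron was not separated from these. Single low-Xist rats not fed iron also reached the 6-day levels. Control rat 3 had Dbp at 9.39 and Bmal1 at 11.80, and deficient rat 3 had 9.97 and 11.37. The 6-day rats had 9.51 to 10.44 and 10.88 to 11.56. In the other control and deficient samples Dbp was at 10.96 to 12.48.

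Asns and Chac1, genes of the amino acid response, drew attention in Belgrade rats with differences of 1.62 and 1.32 that did not pass (limma, adjusted p = 0.0985 and 0.144). A coordinated rise may be present there, since 26 other genes of that response had a camera p of 0.0167 with an estimated correlation and a median of 0.25, a hypothesis from the same data. In iron-deficient rats the p was 0.457 with a median of 0.07, although Trib3, 1 of the 26, rose by 1.74 (limma, adjusted p = 0.0350). It was the only member that passed in either comparison, and in Belgrade rats it differed by 1.49 (adjusted p = 0.278).

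Other splits of the same samples were fitted with limma for each count. For iron deficiency the real split gave 107 and the highest of the others 68, as 1 of 35 splits. This is the smallest share that 35 splits can give. The count also fell to 0 without deficient rat 2 and to 0 without a trend, so chance is not excluded for it. For top against bottom over all groups the real count was 14382 against 0, as 1 of 100 drawn splits, which argues against chance there. A real count of 0 is reached by every split by construction, so the splits do not bear on chance there. This holds for repletion against deficiency (35 of 35 splits, 3385 at an unadjusted p under 0.05), 3 days of iron (35 of 35, 730), the interaction (100 of 100, 1956) and the deficiency effect between segments (35 of 35, 2396). The highest counts of their other splits were 835, 77, 28 and 2, and those of 835, 77 and 28 point to a structure of the samples. The splits were too few for a share under 0.05 in the others. Repletion against control had 18 against 16 (1 of 10), Belgrade 3 against 1 (1 of 10), 6 days of iron 0 against 0 (10 of 10, with 1120 at an unadjusted p), the Belgrade effect between segments 0 against 0 (10 of 10, with 1711) and top against bottom in controls 6420 against 1 (1 of 4).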
